A study of Homo sapiens with 15 samples.

How the data were processed

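Per the labels' protocols, RNA was taken from A375 cells with Trizol and 1 µg of total RNA went into Illumina TruSeq stranded mRNA libraries, which select poly(A) RNA. Per the submitters' processing notes, Bowtie2, TopHat2 2.0.9, Cufflinks 2.2.0 and Cuffdiff were used with the genome build GRCh37; the notes give no role for each. The authors' deposited matrix holds FPKM (fragments per kilobase of transcript, scaled to the mapped fragments) for protein-coding genes in each of the 15 libraries. No header names the unit. It was read from the values, whose totals per library are unequal, and from column names that mark Cufflinks output. The matrix gives gene symbols without identifiers or positions, and the annotation at hand is of another build, so no coordinates are given. Every library was matched to its label by the name of its column. Low values did not recover whole numbers of fragments, so counts were not rebuilt, depth is unknown, and no counting intervals or detection limits are given.

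Of 18680 genes, 27 whose symbols had turned into dates were left out, which left 18653. Genes with at least 1 FPKM in at least 3 libraries were tested, 12028 in all. Libraries were checked for shared values: no pair had more than 0.00650% identical nonzero values. Values were used as log2(FPKM + 1) with no further scaling between libraries. The choices given in this and the next 2 paragraphs were made before the data were examined.

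All tests of single genes used limma 3.58.1 in R 4.3.3, with a mean for each of 5 groups, 10 residual degrees of freedom, an intensity trend in the variance prior (5.99 prior degrees of freedom) and two-sided p-values adjusted by the Benjamini-Hochberg method over the genes tested in each of 5 comparisons. A gene was called changed at an adjusted p under 0.05. Gene lists were tested with camera in limma, with a preset correlation of 0.01 between genes and, as an alternative, with an estimated correlation, adjusted over the lists of each comparison. Another list test of limma, fry, was planned beside it. Its counts are given with the results on processing, and list results elsewhere are those of camera. Overlaps between comparisons were tested with Fisher's exact test, two-sided, adjusted over 3 pairs. Where 2 comparisons shared libraries, 100 sets were simulated from the residuals without group differences, and, after the results were seen, 100 that kept the group differences but shuffled those of SMAD1 within 20 bins of level. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

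The genes named are the 6 largest rises and falls in the comparisons for the GDF6 knockdown label, SMAD1 and GDF6 overexpression and the 3 largest in the other 2, among called genes with values that do not overlap between groups and a mean of at least 2 FPKM, with 14 genes always named and up to 4 members of smallest p in each list. Genes named beyond this rule (MSX1, SNAI2, TYR, SLC7A11, HSPA5 and DDIT3 in the overlap, the class II genes, and the genes given for changes in 3 comparisons) were chosen after their values were seen. Some genes that the rule names are not reported here. The 30 lists fixed beforehand were BMP target genes; BMP ligands, receptors and SMADs; melanocyte differentiation and pigmentation; neural crest regulators; pro-apoptotic and anti-apoptotic genes; the dedifferentiated melanoma state; TGF-beta, Notch, Wnt and p53 target genes; ERK pathway output; extracellular matrix; S phase and G2 and M phase genes; interferon-stimulated genes; NF-kappaB and inflammatory cytokine genes; the unfolded protein and amino acid response; sterol synthesis; glycolysis and hypoxia response; bone and cartilage, neuronal and glial genes; cytosolic ribosomal proteins; mitochondrially encoded genes; replication-dependent histones; immediate early genes; and epithelial, fibroblast, endothelial and leukocyte markers. Lists with at least 5 tested members were tested, which left out the endothelial (4) and leukocyte (3) markers.

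The method was tested on simulated data made from these libraries with changes of known size. A log2 change of 1 was recovered for 100% of genes in 4 comparisons and for 98.5% with GDF6 overexpression. A change of 0.5 was recovered for 59.7% in the comparison of the libraries labelled GDF6 knockdown with EGFP knockdown, 80.6% for SMAD1 against those libraries, 62.7% for SMAD1 against EGFP knockdown, and 68.7% for GDF6 overexpression and for EGFP knockdown against the empty vector. Unchanged genes were called in 0.0507% to 0.110% of cases. Of 200 genes moved in opposite directions 199 were called so, with 0 others. A shift of 0.3 in the sterol synthesis list gave an adjusted p of 3.7e-26 in the list test, with 0 other lists called. The simulated noise was drawn for each gene on its own, so these list results do not measure false calls among correlated genes. The correlations estimated from the real libraries ran from 0.00376 (melanocyte genes) to 0.764 (cytosolic ribosomal proteins), with 0.107 for sterol synthesis. The alternatives tried were a pseudocount of 0.1, no filter or a filter of 5 FPKM, quantile normalization, median-ratio scaling, a block for the replicate number, no variance trend, a fit of the compared groups alone, a fold threshold of 2, the estimated correlation, and leaving out each library in turn.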

Results

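Transcripts were measured by RNA sequencing of poly(A) RNA in 15 libraries from A375 cells, a human melanoma cell line. The libraries fell into 5 groups of 3. By their labels, the cells of the first group carried an empty vector, and those of the second overexpressed GDF6, a secreted ligand of the bone morphogenetic protein (BMP) family. The third group carried the empty vector with a knockdown of EGFP, a jellyfish gene that human cells lack, as the control for the fourth group, which carried the empty vector with a knockdown of GDF6. The fifth group combined the knockdown of GDF6 with overexpression of SMAD1, a transcription factor that carries BMP signals to the nucleus. Per the labels' protocols the SMAD1 construct was SMAD1DVD, and each construct was stable. The deposited values are FPKM, so total counts and depth are unknown and no counting intervals are given. Total FPKM was 542285 to 551483 in the empty vector libraries, 502880 to 565559 with GDF6 overexpression, 423703 to 463938 with EGFP knockdown, 416623 to 448506 in the libraries labelled GDF6 knockdown and 415705 to 446391 with SMAD1 added. Levels below are mean FPKM ± SD (n = 3 libraries), and changes are log2 fold changes of FPKM + 1 with ± SE and the adjusted p of limma. The largest rises and falls named are those among changed genes whose values do not overlap between the groups and whose mean over the 15 libraries is at least 2 FPKM. These fold changes understate changes of genes with low FPKM. The labels do not say that the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

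Across 12028 tested genes, Spearman correlation gave a median of 0.992 between empty vector and GDF6 overexpression libraries and 0.970 between the libraries labelled GDF6 knockdown with and without SMAD1. The medians were 0.907 between EGFP knockdown libraries and those labelled GDF6 knockdown and 0.881 between empty vector and EGFP knockdown libraries. Pairs within a group ran from 0.983 to 0.998; genes are not independent replicates, so no p is given. The first principal component held 62.9% of the variance and the second 22.8%. The mitochondrially encoded genes held 10.8% to 12.6% of total FPKM in the EGFP knockdown libraries, 7.54% to 10.3% in the libraries labelled GDF6 knockdown and 6.14% to 6.74% with SMAD1 added. Their share was 7.30% to 7.67% in the empty vector libraries and 6.38% to 9.63% with GDF6 overexpression, where library 2 stood apart at 9.63%.

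The targeted genes were read first. GDF6 was at 3536 ± 330.4 FPKM with the overexpression construct against 2.49 ± 1.93 with the empty vector (log2 fold change 10.11 ± 0.23, adjusted p = 4.9e-14). In the libraries labelled GDF6 knockdown, GDF6 was at 0.971 ± 0.159 FPKM against 0.856 ± 0.108 with EGFP knockdown (log2 fold change 0.09 ± 0.23, adjusted p = 0.766). The transcript was thus not lower there, and this group is called the libraries labelled GDF6 knockdown throughout. GDF6 fell to 0.0436 ± 0.0193 FPKM where SMAD1 was added (−0.91 ± 0.23, adjusted p = 0.00778 against the libraries labelled GDF6 knockdown). The 3 empty vector libraries ranged from 1.30 to 4.71 FPKM for GDF6. SMAD1 was at 439 ± 19.1 FPKM in the libraries given SMAD1 and at 2.57 ± 0.297 in the libraries labelled GDF6 knockdown (6.95 ± 0.09, adjusted p = 8.3e-18). The EGFP transcript is not among the human genes listed.

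**Figure D1:**
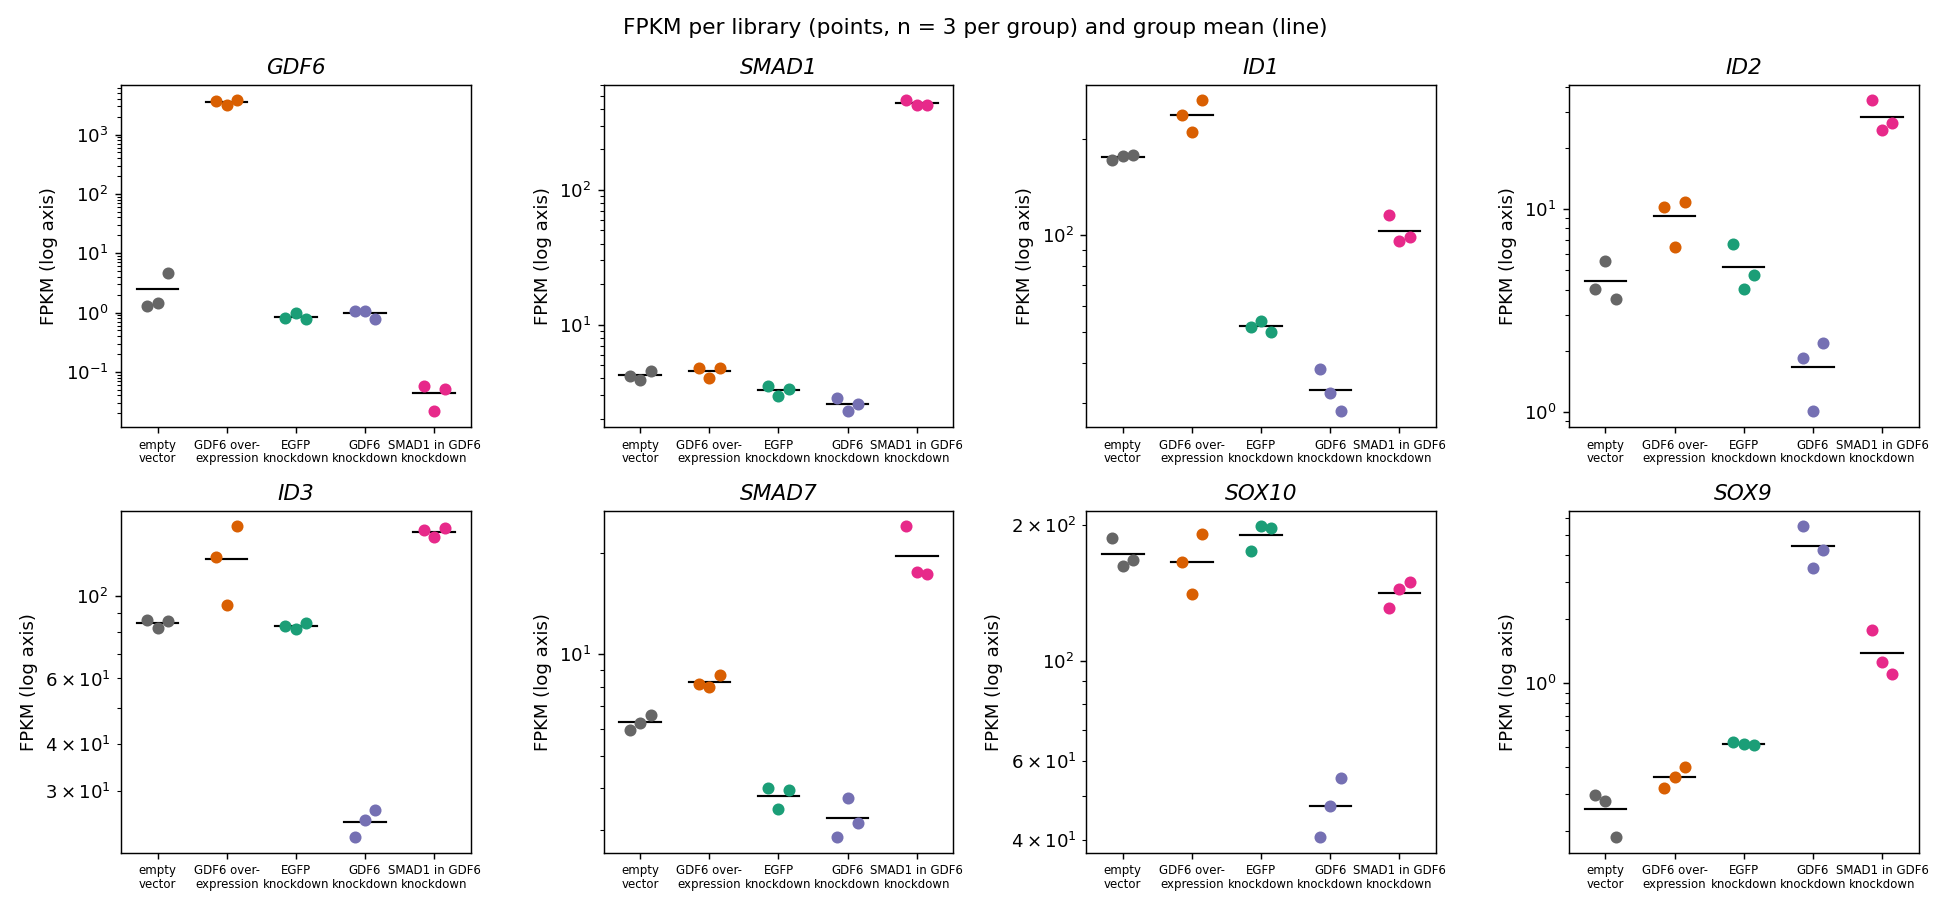
FPKM of GDF6, SMAD1, ID1, ID2, ID3, SMAD7, SOX10 and SOX9 on a log axis in the 5 groups; each point is 1 of 15 libraries and each line a group mean. GDF6 sits at a mean of 3536 FPKM in the overexpression libraries, and at 0.856 and 0.971 FPKM in the EGFP knockdown libraries and those labelled GDF6 knockdown.

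What changes when GDF6 is knocked down was asked by comparing the libraries labelled GDF6 knockdown with the EGFP knockdown libraries; directions follow the labels, since the GDF6 transcript was not lower. DCT, an enzyme of melanin synthesis, fell from 9.67 ± 1.27 to 0.0704 ± 0.0550 FPKM (log2 fold change −3.31 ± 0.09, adjusted p = 1.2e-13). It was at 0.0956 ± 0.0165 FPKM with the empty vector and 0.0672 ± 0.0288 with GDF6 overexpression. The fall of DCT is thus from a level that only the EGFP knockdown libraries had. SOX10, the transcription factor that drives melanocyte genes, fell from 190.4 ± 13.4 to 47.7 ± 7.11 FPKM (−1.98 ± 0.12, adjusted p = 6.2e-10). HERPUD1, a gene of protein quality control in the endoplasmic reticulum, rose to 494 ± 23.1 against 31.7 ± 1.74 FPKM (3.92 ± 0.13, adjusted p = 6.4e-13), and the cytokine IL6 to 15.7 ± 0.979 against 0.107 ± 0.140 (3.92 ± 0.11, adjusted p = 1.4e-13). The BMP targets ID1, ID2 and ID3, which encode inhibitors of differentiation, each fell.

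The largest rises were those of CPA4, a carboxypeptidase, at 596 ± 32.7 against 17.6 ± 3.84 FPKM (5.02 ± 0.12, adjusted p = 2.3e-14), and SERPINB7, a protease inhibitor, at 116 ± 6.75 against 3.00 ± 0.353 (4.87 ± 0.11, adjusted p = 2.3e-14). GDF15, a stress-induced cytokine, was at 96.3 ± 7.56 against 2.54 ± 0.663 FPKM (4.80 ± 0.12, adjusted p = 3.9e-14), and DUSP5, a phosphatase induced by ERK, at 89.9 ± 11.8 against 4.28 ± 0.296 (4.10 ± 0.10, adjusted p = 3.9e-14). The largest falls included TCN1, a vitamin B12 carrier, from 79.5 ± 3.53 to 1.95 ± 0.314 FPKM (−4.77 ± 0.15, adjusted p = 5.0e-13), and ANGPTL7, a secreted glycoprotein, from 20.97 ± 4.66 to 0.0982 ± 0.0398 (−4.30 ± 0.12, adjusted p = 1.4e-13). HMCN1, a matrix protein (−4.20 ± 0.16, adjusted p = 3.7e-12), and SERPINA3 (−4.13 ± 0.21, adjusted p = 9.7e-11) also fell. So did the receptor phosphatase PTPRZ1 (−4.06 ± 0.16, adjusted p = 5.1e-12) and ENPP2, which makes lysophosphatidic acid (−4.03 ± 0.18, adjusted p = 1.6e-11).

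In the list of melanocyte differentiation and pigmentation genes, 4 of 18 rose and 12 fell (median log2 fold change −0.57), among them EDNRB (−1.82 ± 0.10, adjusted p = 1.2e-10), GPNMB (−1.33 ± 0.08, adjusted p = 1.1e-09) and RAB38 (−1.65 ± 0.12, adjusted p = 8.6e-09). The list test gave adjusted p = 0.0314, and adjusted p = 0.131 with an estimated correlation. MITF, the factor that heads this program, rose from 13.6 ± 0.980 to 22.6 ± 0.932 FPKM (0.70 ± 0.09, adjusted p = 4.4e-06), and TYR was at 0.0900 FPKM or less in every one of the 15 libraries and was not tested. Of 20 neural crest regulators 6 rose and 10 fell (list adjusted p = 0.271). TFAP2B fell from 47.4 ± 3.89 to 3.09 ± 0.660 FPKM (−3.57 ± 0.13, adjusted p = 1.3e-12) and the receptor ERBB3 from 189 ± 3.75 to 22.1 ± 3.05 (−3.05 ± 0.13, adjusted p = 9.7e-12). SNAI2, not tested, was at 0.0577 ± 0.0262 against 0.456 ± 0.0865 FPKM. Of 13 neuronal and glial genes 5 rose and 7 fell (list adjusted p = 0.498). The Schwann cell genes S100B (−3.47 ± 0.16, adjusted p = 2.0e-11) and CDH19 (−3.36 ± 0.13, adjusted p = 5.1e-12) fell. Of the 13 genes of this list the EGFP knockdown control was itself higher than the empty vector for 10 and lower for 3. SOX9, a regulator of cartilage and of neural crest cells, rose from 0.517 ± 0.00735 to 4.41 ± 1.01 FPKM (1.82 ± 0.12, adjusted p = 2.5e-09).

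Of 19 BMP target genes 6 rose and 8 fell (list adjusted p = 0.598). ID1 fell from 52.0 ± 2.07 to 32.9 ± 5.08 FPKM (−0.65 ± 0.11, adjusted p = 6.7e-05) and ID2 from 5.16 ± 1.39 to 1.67 ± 0.601 (−1.21 ± 0.21, adjusted p = 0.000109). ID3 fell from 82.9 ± 1.54 to 24.7 ± 2.04 (−1.71 ± 0.12, adjusted p = 5.3e-09). BAMBI (−1.58 ± 0.10, adjusted p = 9.2e-10), DLX2 (−1.38 ± 0.09, adjusted p = 1.2e-09) and HEY1 (−2.57 ± 0.18, adjusted p = 4.2e-09) fell too. SMAD6, an inhibitor of the pathway, rose (0.52 ± 0.10, adjusted p = 0.000378), as did MSX1 (1.47 ± 0.11, adjusted p = 1.1e-08). SMAD7 had a log2 fold change of −0.18 ± 0.11 (adjusted p = 0.188). Among 20 BMP ligands, receptors and SMADs 9 rose and 5 fell (list adjusted p = 0.115), with RGMB (2.11 ± 0.08, adjusted p = 4.3e-12) and BMP2 (1.48 ± 0.10, adjusted p = 1.3e-09) higher. SMAD1 itself had a log2 fold change of −0.26 ± 0.09 and adjusted p = 0.0227, which became 0.0867 without EGFP knockdown library 1, 0.0568 without library 3 of that group and 0.107 without library 2 labelled GDF6 knockdown (range over the alternatives 0.00978 to 0.261).

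The list of the unfolded protein and amino acid response, genes induced by misfolded protein or by lack of amino acids, rose most by its test: 19 of 25 rose and 4 fell. The median was 1.53 and the list test gave adjusted p = 8.0e-06, and adjusted p = 0.128 with an estimated correlation. ATF3 (2.76 ± 0.09, adjusted p = 9.9e-13), DNAJB9 (2.98 ± 0.12, adjusted p = 6.6e-12) and PDIA4 (1.94 ± 0.08, adjusted p = 3.8e-12) rose, and SLC7A11, a cystine carrier, fell (−1.99 ± 0.15, adjusted p = 1.3e-08). The EGFP knockdown control was itself lower than the empty vector for 14 of these 25 genes and higher for 7. Of 23 sterol synthesis genes 14 rose and 2 fell. The median was 0.70 and the list test gave adjusted p = 0.00185, and adjusted p = 0.203 with an estimated correlation. Among them were INSIG1 (2.001 ± 0.10, adjusted p = 5.5e-11) and DHCR7 (1.63 ± 0.10, adjusted p = 5.7e-10). The count of 2 became 1 without EGFP knockdown library 2. Of 23 p53 target genes 14 rose and 5 fell, and 14 and 6 adjusted over the list alone. The median was 0.65 and the list test gave adjusted p = 0.00315, and adjusted p = 0.174 with an estimated correlation. CDKN1A, an inhibitor of the cell cycle, was at 252 ± 39.9 against 72.4 ± 4.78 FPKM (1.78 ± 0.11, adjusted p = 1.1e-09), and BTG2 (2.45 ± 0.08, adjusted p = 9.9e-13) and FAS (1.31 ± 0.09, adjusted p = 1.4e-09) rose. Of 21 NF-kappaB and inflammatory cytokine genes 15 rose and 5 fell, and 16 and 5 adjusted over the list alone. The median was 0.87 and the list test gave adjusted p = 0.00315, and adjusted p = 0.128 with an estimated correlation. MMP3 (2.88 ± 0.11, adjusted p = 2.1e-12) and IL24 (2.29 ± 0.13, adjusted p = 4.2e-10) rose, while IL1B fell from 5.68 ± 1.29 to 0.422 ± 0.101 FPKM (−2.21 ± 0.12, adjusted p = 1.8e-10). IL24 was itself lower with EGFP knockdown than with the empty vector, as given below.

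Of 14 replication-dependent histones 9 rose and 2 fell, the latter 1 without any single library of the comparison. The median was 0.88 and the list test gave adjusted p = 0.0078, and adjusted p = 0.131 with an estimated correlation. HIST2H2BE (1.82 ± 0.08, adjusted p = 2.0e-11) and HIST1H4H (1.26 ± 0.11, adjusted p = 4.0e-08) rose; poly(A) selection captures few histone transcripts, so these values cover the polyadenylated ones. Of 41 S phase genes 18 rose and 2 fell, and 17 and 2 adjusted over the list alone. The median was 0.18 and the list test gave adjusted p = 0.0414, and adjusted p = 0.726 with an estimated correlation. This call was lost without EGFP knockdown library 1 (0.0580) or 3 (0.0939) and without library 2 labelled GDF6 knockdown (0.0898; range over the alternatives 0.00621 to 0.0939). CDC25A (1.08 ± 0.09, adjusted p = 2.8e-08) and PCNA (0.62 ± 0.08, adjusted p = 7.6e-06) rose. The EGFP knockdown control was itself lower than the empty vector for 37 of these 41 genes and higher for 0. Of 43 G2 and M phase genes 9 rose and 4 fell, and 8 and 4 adjusted over the list alone (adjusted p = 0.498); 1 fell without EGFP knockdown library 2 and 2 without library 1 labelled GDF6 knockdown. CKS2 (0.85 ± 0.13, adjusted p = 3.8e-05) and AURKB (0.61 ± 0.13, adjusted p = 0.000548) rose.

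Of 33 extracellular matrix genes 7 rose and 19 fell, and 8 and 19 adjusted over the list alone. The median was −0.49 and the list test gave adjusted p = 0.0414, and adjusted p = 0.726 with an estimated correlation. VCAN (−3.40 ± 0.16, adjusted p = 2.5e-11), TIMP3 (−2.27 ± 0.11, adjusted p = 5.8e-11) and COL8A1 (−2.63 ± 0.15, adjusted p = 4.5e-10) fell. The call was lost without EGFP knockdown library 1 or 3 (0.0580 each) and without library 3 labelled GDF6 knockdown (0.0545). Its adjusted p ranged from 0.0149 to 0.0580 over the alternatives. The EGFP knockdown control was itself higher than the empty vector for 29 of these 33 genes and lower for 1. Of 30 interferon-stimulated genes 3 rose and 15 fell. The median was −0.31 and the list test gave adjusted p = 0.0481, and adjusted p = 0.377 with an estimated correlation. IFITM1 (−2.01 ± 0.19, adjusted p = 1.4e-07), IFIT1 (−1.49 ± 0.11, adjusted p = 4.4e-09) and PARP9 (−1.37 ± 0.09, adjusted p = 1.3e-09) fell. This call was lost without EGFP knockdown library 1 (0.0580) or 3 (0.0857) and without library 1 (0.0560), 2 (0.0538) or 3 (0.0548) labelled GDF6 knockdown; the range over the alternatives was 0.0135 to 0.338. The count of 3 became 1 without EGFP knockdown library 2 or without library 2 labelled GDF6 knockdown. Of these 30 genes the EGFP knockdown control was itself higher than the empty vector for 20 and lower for 5.

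Of 13 mitochondrially encoded genes 0 rose and 7 fell. The median was −0.37 and the list test gave adjusted p = 0.0479, and adjusted p = 0.726 with an estimated correlation. MT-CO3 was at 3938 ± 301 against 6982 ± 555 FPKM (−0.83 ± 0.12, adjusted p = 1.5e-05). These genes held 7.54% to 10.3% of total FPKM in the libraries labelled GDF6 knockdown and 10.8% to 12.6% with EGFP knockdown. Without EGFP knockdown library 1 the list gave 0.0714, without library 3 of that group 0.0726, without library 2 labelled GDF6 knockdown 0.111 and without library 3 so labelled 0.0545, with a range of 0.0135 to 0.658 over the alternatives. The count of 7 became 4 without EGFP knockdown library 1 or library 2 labelled GDF6 knockdown. Of 41 cytosolic ribosomal proteins 0 rose and 6 fell, and 0 and 2 adjusted over the list alone (adjusted p = 0.254), led by RPLP0 (−0.70 ± 0.16, adjusted p = 0.00126). The count of 6 was 3 without EGFP knockdown library 3 and 10 without library 2 labelled GDF6 knockdown.

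Several lists held genes that rose beside genes that fell and did not pass the list test. Of 25 genes of the dedifferentiated melanoma state 11 rose and 8 fell, and 13 and 8 adjusted over the list alone (adjusted p = 0.143), with BDNF (2.63 ± 0.09, adjusted p = 1.1e-12) and CYR61 (2.24 ± 0.09, adjusted p = 7.1e-12) higher. Of 20 TGF-beta target genes 6 rose and 9 fell, and 7 and 9 adjusted over the list alone (adjusted p = 0.957). The median was −0.20 while the test pointed up, CTGF rose (2.43 ± 0.13, adjusted p = 1.2e-10) and FN1 fell (−1.52 ± 0.09, adjusted p = 5.3e-10). Of 19 genes of ERK pathway output 8 rose and 7 fell, and 8 and 8 adjusted over the list alone (adjusted p = 0.654), with a median of −0.15 and a mean of 0.31. CCND1 (1.70 ± 0.10, adjusted p = 4.2e-10) and SPRY1 (1.76 ± 0.11, adjusted p = 6.7e-10) rose. Of 23 immediate early genes 12 rose and 7 fell (adjusted p = 0.0682, range over the alternatives 0.0400 to 0.157), and EGR1 fell from 10.5 ± 1.83 to 2.79 ± 0.311 FPKM (−1.60 ± 0.11, adjusted p = 2.9e-09). Of 7 epithelial markers 5 rose and 1 fell (adjusted p = 0.101), with KRT18 (1.38 ± 0.13, adjusted p = 1.4e-07) higher. Of 5 Notch target genes 1 rose and 2 fell (adjusted p = 0.654), with HES1 lower (−1.98 ± 0.27, adjusted p = 9.3e-06), and of 6 Wnt target genes 2 rose and 2 fell (adjusted p = 0.791), with TNFRSF19 lower (−2.55 ± 0.07, adjusted p = 2.3e-13). The Wnt list had a median of 0.00 and a mean of −0.34.

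Of 23 pro-apoptotic genes 8 rose and 6 fell (adjusted p = 0.564). The death receptor TNFRSF10A (1.41 ± 0.09, adjusted p = 1.0e-09), PMAIP1 (1.09 ± 0.09, adjusted p = 2.9e-08) and BBC3 (1.28 ± 0.11, adjusted p = 5.4e-08) rose. BCL2L11, which encodes BIM, was at 5.16 ± 1.12 against 5.37 ± 0.571 FPKM (−0.06 ± 0.12, adjusted p = 0.684). Of 10 anti-apoptotic genes 3 rose and 4 fell (adjusted p = 0.654), with BCL2L1 higher (1.03 ± 0.11, adjusted p = 8.5e-07). Of 30 genes of glycolysis and the hypoxia response 10 rose and 12 fell (adjusted p = 0.882), with ADM (2.08 ± 0.13, adjusted p = 1.5e-09) higher and BNIP3 (−1.19 ± 0.11, adjusted p = 1.6e-07) lower. Of 10 bone and cartilage genes 4 rose and 5 fell, and 4 and 6 adjusted over the list alone (adjusted p = 0.654). Of 13 fibroblast markers 2 rose and 5 fell (adjusted p = 0.506), with PRRX1 lower (−1.77 ± 0.14, adjusted p = 1.6e-08). The EGFP knockdown control was itself higher than the empty vector for 12 of these 13 markers and lower for 1. PRRX1 had a mean of 87.3 FPKM with EGFP knockdown and 13.2 with the empty vector. Of 4 endothelial markers 1 rose and 2 fell, with FLT1 lower (−2.94 ± 0.10, adjusted p = 8.4e-13), and of 3 leukocyte markers 0 rose and 2 fell, with CD74 lower (−2.48 ± 0.17, adjusted p = 2.4e-09); these 2 lists were too short for a list test.

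In this comparison 3579 genes were higher and 3827 lower in the libraries labelled GDF6 knockdown, and 649 and 977 of them by at least 2-fold. The excess of lower genes turned with the scaling, with 4033 higher and 3618 lower after quantile normalization and 3907 and 3661 after median-ratio scaling. The 3 values of a group lay wholly outside the 3 of the other for 62.5% of genes, against 10% by chance. Of the 28 lists tested 10 passed, and 6 did so without EGFP knockdown library 1 or 3. No list that passed here kept its call with an estimated correlation.

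**Figure D2:**
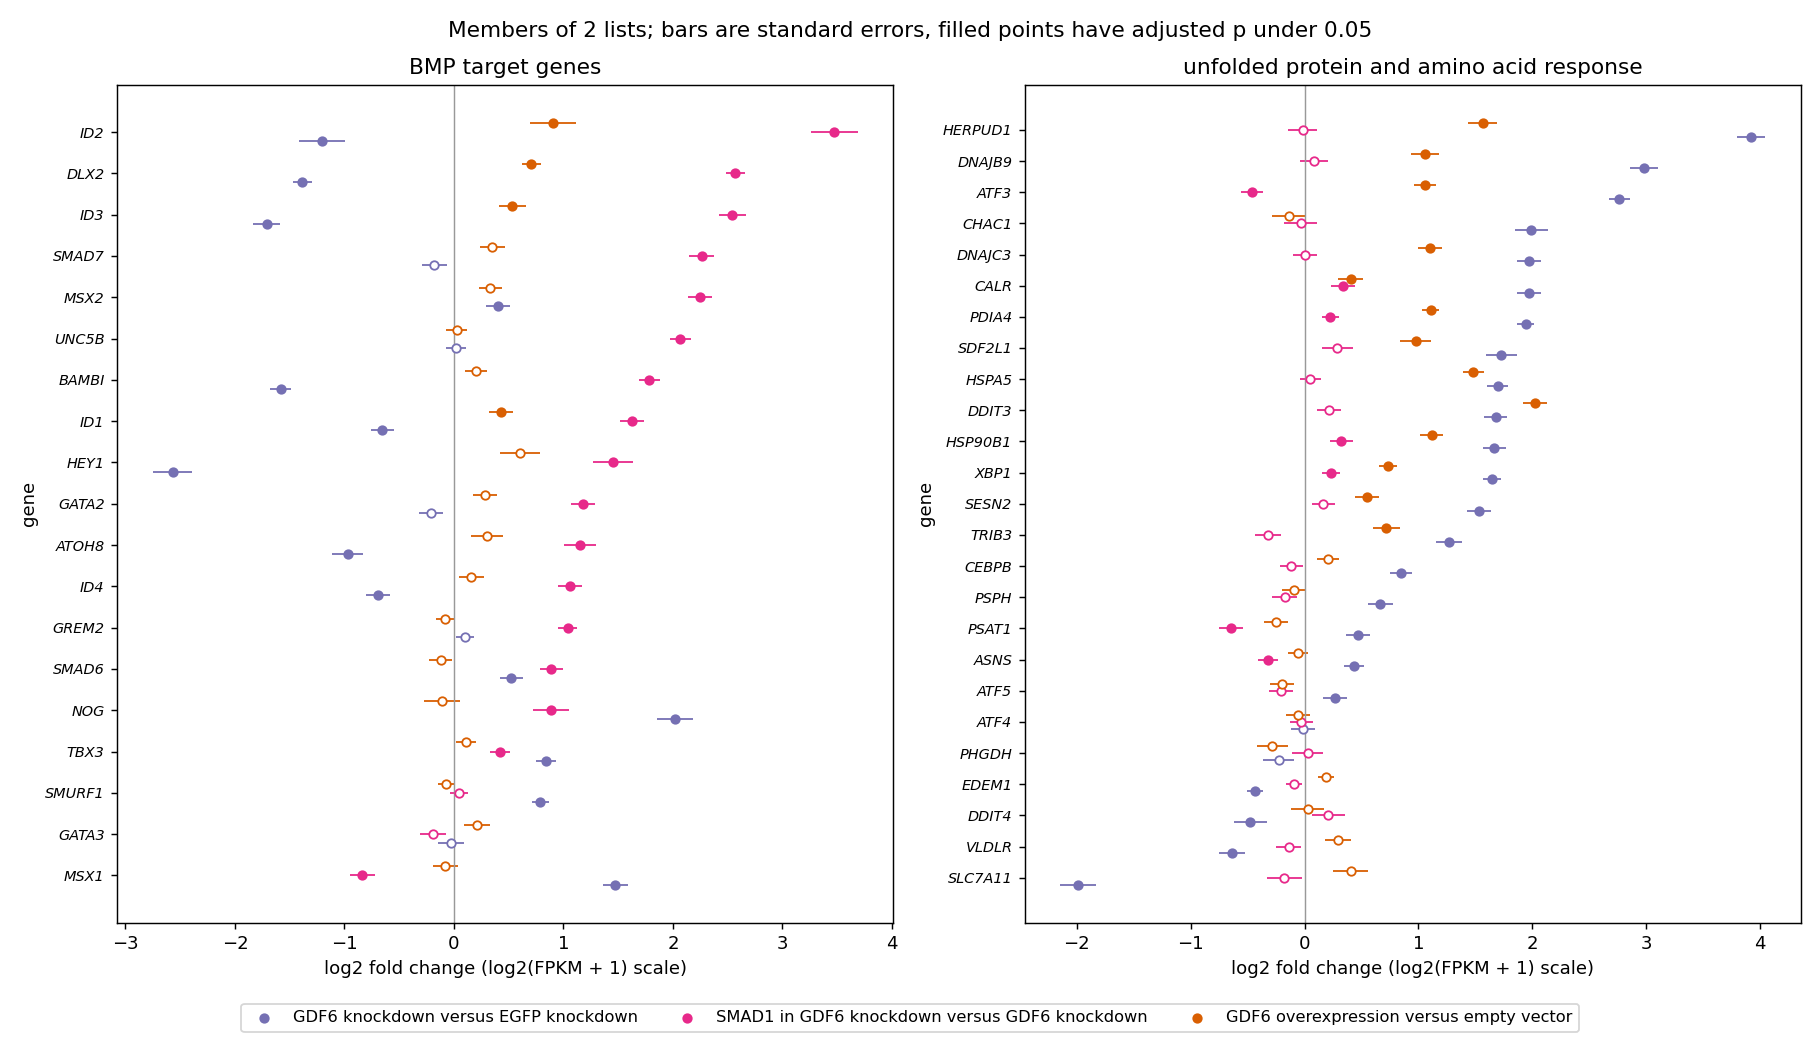
Log2 fold changes on the log2(FPKM + 1) scale of the members of 2 lists in the comparisons of the libraries labelled GDF6 knockdown, of SMAD1 added and of GDF6 overexpression; each point is 1 gene, bars are standard errors, and filled points have an adjusted p under 0.05. Of 19 BMP target genes 16 rose with SMAD1, and of 25 unfolded protein and amino acid response genes 19 rose in the libraries labelled GDF6 knockdown and 13 with GDF6 overexpression.

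What returns when the downstream pathway is reactivated was asked by comparing the libraries given SMAD1 with those labelled GDF6 knockdown; GDF6 itself was lower in the former. BMP target genes rose with SMAD1. ID1 went from 32.9 ± 5.08 to 104 ± 10.6 FPKM (log2 fold change 1.63 ± 0.11, adjusted p = 1.1e-08). ID2 went from 1.67 ± 0.601 to 28.4 ± 5.08 (3.48 ± 0.21, adjusted p = 3.7e-09) and ID3 from 24.7 ± 2.04 to 149 ± 4.22 (2.54 ± 0.12, adjusted p = 2.8e-10). The inhibitors SMAD6 (0.89 ± 0.10, adjusted p = 7.2e-06) and SMAD7 (2.26 ± 0.11, adjusted p = 4.1e-10) rose as well. SOX10 rose from 47.7 ± 7.11 to 141 ± 9.64 FPKM (1.56 ± 0.12, adjusted p = 6.7e-08) and SOX9 fell from 4.41 ± 1.01 to 1.38 ± 0.354 (−1.18 ± 0.12, adjusted p = 2.0e-06). DCT was at 0.0825 ± 0.00424 against 0.0704 ± 0.0550 (0.02 ± 0.09, adjusted p = 0.921).

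Of 19 BMP target genes 16 rose and 1 fell. The median was 1.18 and the list test gave adjusted p = 1.6e-17, and adjusted p = 0.0110 with an estimated correlation. DLX2 (2.57 ± 0.09, adjusted p = 4.6e-12), UNC5B (2.07 ± 0.09, adjusted p = 1.2e-10) and MSX2 (2.25 ± 0.11, adjusted p = 2.5e-10) rose, while MSX1 fell (−0.84 ± 0.11, adjusted p = 3.4e-05). Among 20 BMP ligands, receptors and SMADs 5 rose, SMAD1 itself among them, and 5 fell (adjusted p = 0.460), with BMP6 (1.29 ± 0.10, adjusted p = 8.8e-08) higher and BMP4 (−1.497 ± 0.10, adjusted p = 1.2e-08) lower. The largest rises besides SMAD1 were those of CGA, the subunit shared by glycoprotein hormones, at 353 ± 95.2 against 14.4 ± 1.44 FPKM (4.50 ± 0.16, adjusted p = 5.5e-12), and SAMD11 at 26.3 ± 2.98 against 0.216 ± 0.0535 (4.49 ± 0.10, adjusted p = 1.0e-14). NTS, the precursor of neurotensin, was at 63.8 ± 15.8 against 3.30 ± 0.749 FPKM (3.90 ± 0.15, adjusted p = 2.0e-11). COL9A2, a cartilage collagen, rose by 3.84 log2 units and PPAPDC1A by 3.48. The largest falls were those of MAL2 (−2.65 ± 0.16, adjusted p = 2.9e-09), the protease MME (−2.58 ± 0.17, adjusted p = 1.1e-08) and IL6 (−2.26 ± 0.11, adjusted p = 2.8e-10), followed by ESM1 (−2.17 ± 0.14, adjusted p = 6.0e-09), CPA4 (−2.14 ± 0.12, adjusted p = 1.1e-09) and TNFSF18 (−2.06 ± 0.13, adjusted p = 4.5e-09).

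Of 43 G2 and M phase genes 0 rose and 37 fell, and 0 and 41 adjusted over the list alone. The median was −0.56 and the list test gave adjusted p = 5.6e-14, and adjusted p = 0.162 with an estimated correlation. ANLN (−0.91 ± 0.11, adjusted p = 1.3e-05), KIF23 (−0.78 ± 0.10, adjusted p = 1.4e-05) and CCNA2 (−0.59 ± 0.09, adjusted p = 9.9e-05) fell. Of 41 S phase genes 0 rose and 31 fell, and 0 and 33 adjusted over the list alone. The median was −0.47 and the list test gave adjusted p = 9.2e-11, and adjusted p = 0.162 with an estimated correlation. Among them were RRM2 (−0.86 ± 0.10, adjusted p = 6.8e-06) and MCM4 (−0.75 ± 0.11, adjusted p = 7.2e-05). Of 13 mitochondrially encoded genes 0 rose and 8 fell, and 0 and 10 adjusted over the list alone. The median was −0.47 and the list test gave adjusted p = 3.5e-05, and adjusted p = 0.253 with an estimated correlation; the count of 8 was 5 without SMAD1 library 3. MT-ND4L was at 2934 ± 206 against 4526 ± 533 FPKM (−0.62 ± 0.13, adjusted p = 0.00224). Of 14 histones 0 rose and 2 fell (adjusted p = 0.427), with the 2 at 1 or 0 when single libraries were left out, and of 41 cytosolic ribosomal proteins 0 rose and 0 fell (adjusted p = 0.528), with RPL22 at −0.27 ± 0.11, adjusted p = 0.0935.

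Of 20 TGF-beta target genes 10 rose and 3 fell, and 10 and 4 adjusted over the list alone. The median was 0.38 and the list test gave adjusted p = 0.00032, and adjusted p = 0.119 with an estimated correlation. PMEPA1 (2.74 ± 0.12, adjusted p = 1.2e-10) and COL4A1 (1.38 ± 0.10, adjusted p = 3.3e-08) rose. Of 33 extracellular matrix genes 14 rose and 3 fell, and 15 and 4 adjusted over the list alone. The median was 0.21 and the list test gave adjusted p = 0.00032, and adjusted p = 0.266 with an estimated correlation. MMP1 (1.66 ± 0.11, adjusted p = 7.8e-09) and COL4A2 (1.16 ± 0.11, adjusted p = 6.1e-07) rose and BGN fell (−1.496 ± 0.11, adjusted p = 3.5e-08). Of 5 Notch target genes 3 rose and 0 fell. The median was 1.45 and the list test gave adjusted p = 0.00097, and adjusted p = 0.162 with an estimated correlation. The risers were JAG1 (1.67 ± 0.09, adjusted p = 8.6e-10), HEY1 (1.45 ± 0.18, adjusted p = 1.5e-05) and HES1 (1.61 ± 0.27, adjusted p = 0.000333). Of 6 Wnt target genes 4 rose and 0 fell. The median was 0.50 and the list test gave adjusted p = 0.00108, and adjusted p = 0.119 with an estimated correlation. Among them were TNFRSF19 (1.70 ± 0.07, adjusted p = 1.1e-10) and LEF1 (1.39 ± 0.13, adjusted p = 6.7e-07).

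Of 21 NF-kappaB and inflammatory cytokine genes 2 rose and 14 fell, and 3 and 15 adjusted over the list alone. The median was −0.40 and the list test gave adjusted p = 0.000518, and adjusted p = 0.0780 with an estimated correlation. CXCL1 fell (−1.53 ± 0.10, adjusted p = 6.1e-09), while PTGS2, an enzyme of prostaglandin synthesis, rose from 0.226 ± 0.105 to 11.8 ± 2.36 FPKM (3.38 ± 0.14, adjusted p = 3.3e-11); the count of 14 was 9 without SMAD1 library 1. Of 30 interferon-stimulated genes 1 rose and 12 fell, and 1 and 13 adjusted over the list alone. The median was −0.28 and the list test gave adjusted p = 0.000807, and adjusted p = 0.119 with an estimated correlation. IFI44 (−1.04 ± 0.12, adjusted p = 8.7e-06) and IFIT2 (−0.63 ± 0.09, adjusted p = 4.5e-05) fell and CMPK2 rose (0.67 ± 0.13, adjusted p = 0.00102). Of 25 genes of the dedifferentiated melanoma state 3 rose and 13 fell. The median was −0.40 and the list test gave adjusted p = 0.0112, and adjusted p = 0.254 with an estimated correlation. NRG1 (−1.24 ± 0.12, adjusted p = 1.1e-06) and EGFR (−0.96 ± 0.09, adjusted p = 7.3e-07) fell and INHBA rose (1.02 ± 0.10, adjusted p = 6.7e-07). With a filter of 5 FPKM this list gave 0.0669 (range over the alternatives 0.00492 to 0.0669). Of 7 epithelial markers 0 rose and 4 fell. The median was −0.43 and the list test gave adjusted p = 0.0151, and adjusted p = 0.162 with an estimated correlation. Among them were ELF3 (−1.23 ± 0.10, adjusted p = 1.1e-07) and KRT18 (−0.85 ± 0.13, adjusted p = 0.000135).

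Of 20 neural crest regulators 8 rose and 4 fell. The median was 0.07 and the list test gave adjusted p = 0.00909, and adjusted p = 0.208 with an estimated correlation. TFAP2B (2.08 ± 0.13, adjusted p = 3.9e-09) and SOX5 (1.32 ± 0.10, adjusted p = 7.5e-08) rose. SNAI2 was at 0.408 ± 0.112 FPKM, untested. Of 18 melanocyte genes 6 rose and 2 fell, and 8 and 2 adjusted over the list alone. The median was 0.20 and the list test gave adjusted p = 0.0211, and adjusted p = 0.119 with an estimated correlation. EDNRB (1.54 ± 0.10, adjusted p = 5.7e-09) and GPNMB (0.60 ± 0.08, adjusted p = 5.2e-05) rose, and MITF (−0.44 ± 0.09, adjusted p = 0.00150) and TYRP1 (−0.54 ± 0.11, adjusted p = 0.00134) fell. Without library 3 labelled GDF6 knockdown the melanocyte list gave 0.0655 (range over the alternatives 0.00678 to 0.0655). Of 13 neuronal and glial genes 6 rose and 5 fell (adjusted p = 0.0992, range over the alternatives 0.0216 to 0.463), with S100B (1.88 ± 0.16, adjusted p = 1.5e-07) and CDH19 (1.99 ± 0.13, adjusted p = 1.2e-08) higher; the count of 5 was 3 without SMAD1 library 1.

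Of 25 unfolded protein and amino acid response genes 4 rose and 3 fell (median −0.02, with the test pointing up, adjusted p = 0.976), and ATF3 fell (−0.46 ± 0.09, adjusted p = 0.00167). The count of 4 was 1, 1 and 0 without library 1, 2 or 3 labelled GDF6 knockdown and 0, 1 and 0 without SMAD1 library 1, 2 or 3, and the count of 3 was 5 without library 1 labelled GDF6 knockdown. Of 23 sterol synthesis genes 3 rose and 1 fell (adjusted p = 0.372), and 1 rose without SMAD1 library 1. The risers INSIG1 and FDFT1 gave adjusted p = 0.0770 and 0.0797 without library 1 labelled GDF6 knockdown. ACAT2, which fell, gave 0.133 and 0.117 without library 2 or 3 so labelled and 0.122 and 0.0794 without SMAD1 library 1 or 3. Of 23 p53 target genes 4 rose and 2 fell (adjusted p = 0.0992), with DDB2 higher (0.55 ± 0.10, adjusted p = 0.000894) and FAS lower (−0.37 ± 0.09, adjusted p = 0.00383); 2 rose without library 1 labelled GDF6 knockdown or without SMAD1 library 1. Of 23 pro-apoptotic genes 1 rose and 6 fell (adjusted p = 0.120), with BCL2L11 at 2.85 ± 0.362 FPKM (−0.67 ± 0.12, adjusted p = 0.000707) and PMAIP1 (−0.81 ± 0.09, adjusted p = 4.1e-06) lower. Of 10 anti-apoptotic genes 1 rose and 3 fell (adjusted p = 0.422), with BCL2L1 lower (−0.60 ± 0.11, adjusted p = 0.000902); 1 fell without library 2 labelled GDF6 knockdown or without SMAD1 library 1 or 3.

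Of 23 immediate early genes 8 rose and 7 fell (adjusted p = 0.292), with NR4A1 (2.29 ± 0.13, adjusted p = 1.3e-09) and EGR3 (1.504 ± 0.10, adjusted p = 7.1e-09) higher. Of 19 genes of ERK pathway output 6 rose and 3 fell (adjusted p = 0.0992), with SPRY4 (1.18 ± 0.10, adjusted p = 1.3e-07) higher and DUSP5 (−1.14 ± 0.10, adjusted p = 3.2e-07) lower. Of 30 genes of glycolysis and the hypoxia response 3 rose and 6 fell, and 3 and 10 adjusted over the list alone (adjusted p = 0.135, range over the alternatives 0.0432 to 0.312), with ADM lower (−1.46 ± 0.13, adjusted p = 4.8e-07). Of 10 bone and cartilage genes 3 rose and 4 fell, and 5 and 5 adjusted over the list alone (adjusted p = 0.935). Of 13 fibroblast markers 2 rose and 1 fell (adjusted p = 0.976). The bone and cartilage list had a median of −0.07 and a mean of 0.06, and the immediate early list a median of −0.02 and a mean of 0.18. The endothelial marker FLT1 went from 2.44 ± 0.338 to 24.6 ± 2.39 FPKM (2.89 ± 0.10, adjusted p = 4.6e-12).

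With SMAD1 added 1272 genes were higher and 1527 lower, 247 and 122 of them by at least 2-fold, and the values of the 2 groups did not overlap for 39.1% of genes, against 10% by chance. Over the 5 comparisons, 2 list calls held with an estimated correlation: the BMP targets here, and the unfolded protein and amino acid response with GDF6 overexpression.

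Genes that differed in the libraries labelled GDF6 knockdown were followed into those given SMAD1. Of 7406 such genes, 1555 (20.997%) changed in the opposite direction with SMAD1 and 473 changed further in the same direction. Of the 1626 that differed by at least 2-fold, 646 (39.7%) changed back, 111 changed further and 869 were not past the threshold; 1026 still differed at least 2-fold in the same direction from the EGFP knockdown libraries. Of 14 BMP targets 9 changed back and 4 changed further, and of 16 neural crest regulators 12 and 0. Of 20 S phase genes 15 changed back and 2 further, and of 20 NF-kappaB genes 11 and 4. In the whole S phase list 31 of 41 genes fell with SMAD1 and 0 rose, so the 15 are not set apart from a general fall. Against EGFP knockdown 16 of the 41 ended lower and 6 higher. Of 23 genes of the unfolded protein and amino acid response 3 changed back and 4 further, of 19 p53 targets 2 and 2, and of 16 sterol synthesis genes 2 and 1. The libraries labelled GDF6 knockdown are in both comparisons, which gives opposite signs by noise alone. In 100 sets that kept the changes of both comparisons, but dealt those with SMAD1 out at random among genes of like level, 911 to 2247 genes (mean 1318) changed in opposite directions. The 1555 lie within that range. In the same direction 915 to 1775 genes changed, against 473 observed. The sets called 2910 to 5238 genes changed with SMAD1 (mean 3785), each more than the 2799 observed. Neither count is therefore set against its like, and neither range decides whether reversal exceeds chance. Of the genes changed in both comparisons 76.7% changed in opposite directions, against 46.8% to 62.1% in those sets, which were made after the results were seen. This share cannot decide it either. The sets called more genes with SMAD1 and hold no deviation common to all 3 shared libraries, which gives opposite signs by itself. In 100 sets without differences the covariance of the fold changes had a mean of −0.00941, against −0.109 observed. The Pearson correlation across genes was −0.38 and the mean of the sets without differences −0.49. The 3 shared libraries are too few to give each comparison its own with replicates.

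The libraries given SMAD1 were also compared with the EGFP knockdown libraries. This comparison holds changes that came with SMAD1 as well as those it left in place. SMAD7, BCL2L11 and the G2 and M phase list, for example, passed no threshold in the libraries labelled GDF6 knockdown and changed with SMAD1. CGA, at 353 ± 95.2 against 0.387 ± 0.279 FPKM (log2 fold change 7.98 ± 0.16, adjusted p = 3.1e-15), and GDF15 (4.30 ± 0.12, adjusted p = 2.2e-13) were among the largest rises. ANGPTL7 (−4.40 ± 0.12, adjusted p = 2.1e-13), TCN1 (−3.38 ± 0.15, adjusted p = 2.3e-11) and the sulfate transporter SLC26A2 (−3.26 ± 0.14, adjusted p = 2.1e-11) were the largest falls within that scope. ID1 (0.98 ± 0.11, adjusted p = 9.8e-07), ID2 (2.27 ± 0.21, adjusted p = 1.3e-07), ID3 (0.83 ± 0.12, adjusted p = 2.3e-05), SMAD6 (1.41 ± 0.10, adjusted p = 8.7e-09) and SMAD7 (2.09 ± 0.11, adjusted p = 2.5e-10) rose. DCT (−3.29 ± 0.09, adjusted p = 2.1e-13), SOX10 (−0.43 ± 0.12, adjusted p = 0.00552) and BCL2L11 (−0.73 ± 0.12, adjusted p = 8.6e-05) fell, and SOX9 rose (0.64 ± 0.12, adjusted p = 0.000306). DCT was high only in the EGFP knockdown libraries, at 9.67 ± 1.27 FPKM against 0.0956 ± 0.0165 with the empty vector. MITF gave 0.25 ± 0.09, adjusted p = 0.0215, which became 0.0935 without EGFP knockdown library 1 and 0.0903 without SMAD1 library 3 (range over the alternatives 0.00466 to 0.0935).

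Of 19 BMP targets 15 rose and 1 fell (adjusted p = 1.1e-06, and adjusted p = 0.0690 with an estimated correlation), and of 25 genes of the unfolded protein and amino acid response 16 rose and 3 fell (adjusted p = 1.3e-05, and adjusted p = 0.0690 with an estimated correlation). Of 23 sterol synthesis genes 15 rose and 2 fell (4.9e-05, and adjusted p = 0.0955 with an estimated correlation), and of 23 p53 targets 16 rose and 4 fell (7.6e-05, and adjusted p = 0.0690 with an estimated correlation). The other lists that rose, each with its 2 adjusted p-values in that order, were immediate early genes with 16 and 4 (0.000606, and 0.231), TGF-beta targets with 12 and 3 (0.000978, and 0.158), histones with 9 and 1 (0.00143, and 0.0690) and BMP ligands, receptors and SMADs with 11 and 7 (0.0267, and 0.231). The last list holds SMAD1, which the construct raises, and GDF6, so part of its result is set by the constructs. It had a range of 0.0196 to 0.126 over the alternatives, and its 7 falls were 4 without EGFP knockdown library 2. Lists that fell were mitochondrially encoded genes with 0 up and 12 down (0.000149, and adjusted p = 0.318 with an estimated correlation), G2 and M phase genes with 1 and 34 (0.000222, and 0.593) and interferon-stimulated genes with 1 and 20 (0.000336, and 0.0690). Medians and means or tests differed in sign for neural crest regulators, pro-apoptotic genes and Notch targets, none of them past the threshold. The NF-kappaB list gave adjusted p = 0.0867, and 0.0372 at a filter of 5 FPKM. In this comparison 3431 genes were higher and 4025 lower, against 3859 and 3736 after quantile normalization and 3867 and 3758 after median-ratio scaling, and 68.7% of genes did not overlap, against 10% by chance.

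**Figure D3:**
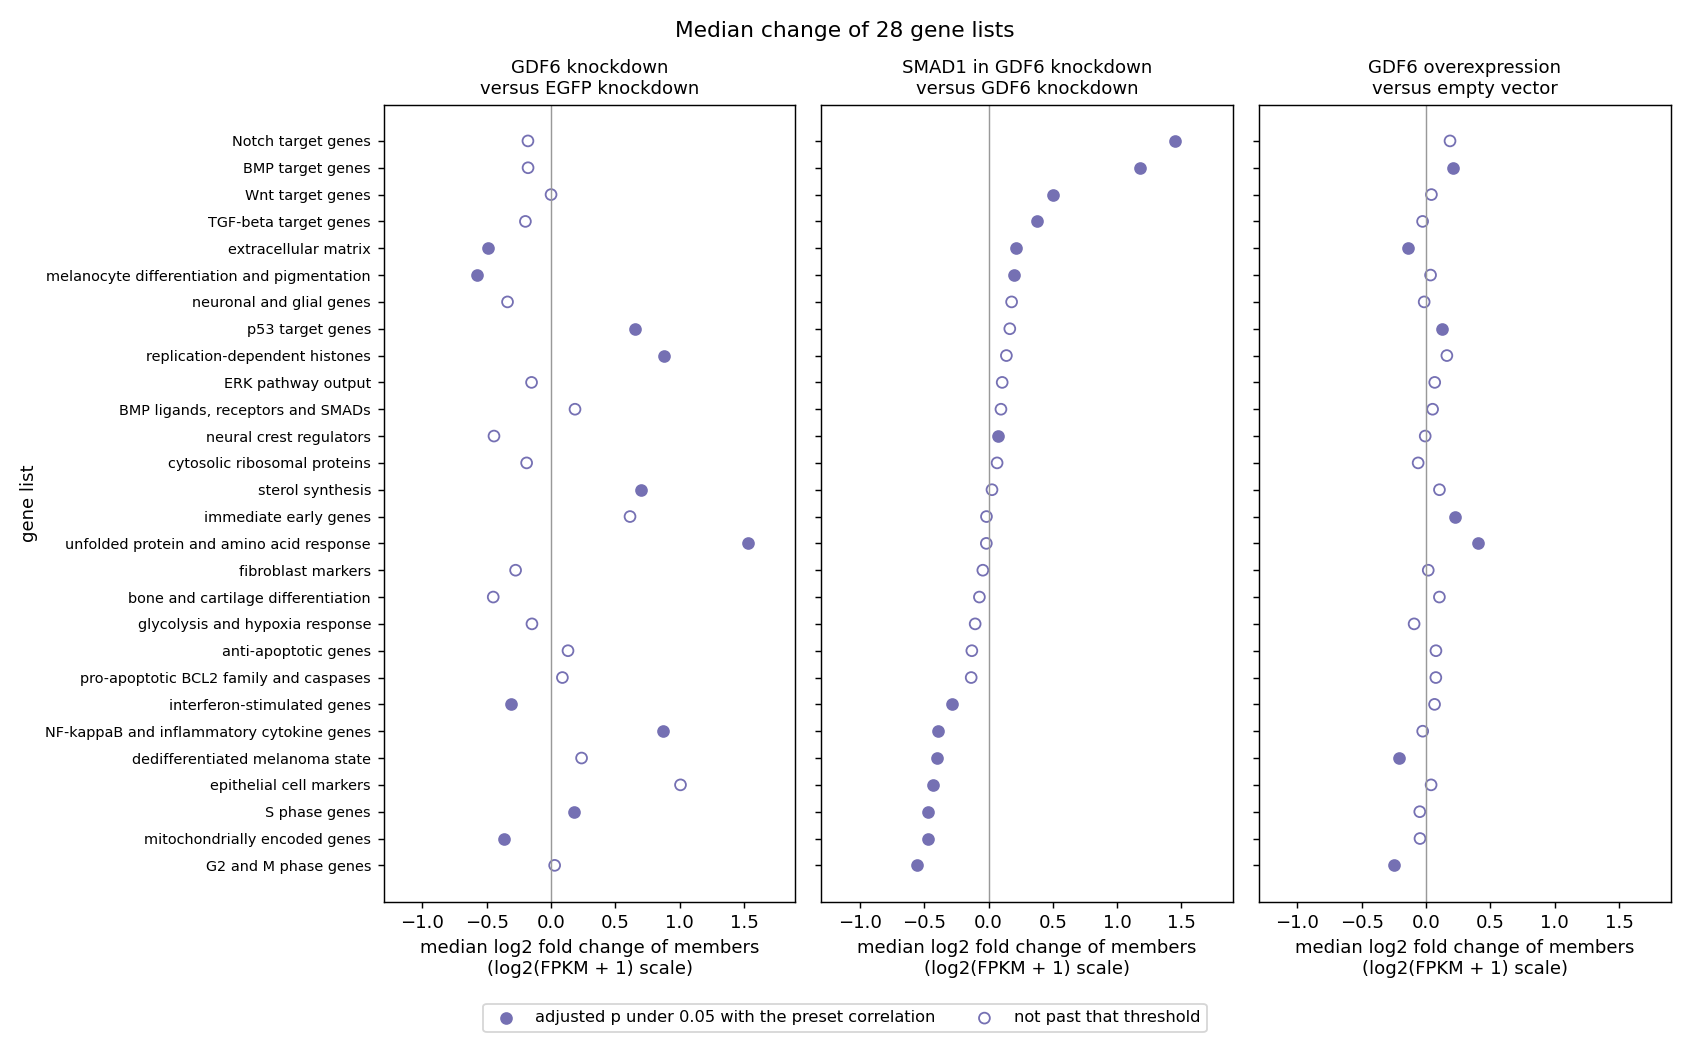
Median log2 fold change of each gene list on the log2(FPKM + 1) scale in the 3 comparisons named above the panels; each marker is the median over the tested members of 1 list, filled where the list test passed with the preset correlation. The median of the BMP targets is 1.18 with SMAD1 and 0.21 with GDF6 overexpression, and that of the unfolded protein and amino acid response is 1.53 in the libraries labelled GDF6 knockdown.

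What more GDF6 does was asked by comparing the GDF6 overexpression libraries with the empty vector libraries. Besides GDF6, genes of the unfolded protein response rose. DDIT3, which encodes CHOP, was at 74.2 ± 9.81 against 17.4 ± 0.215 FPKM (log2 fold change 2.02 ± 0.10, adjusted p = 7.3e-09). The chaperone HSPA5 was at 696 ± 38.7 against 248 ± 4.08 (1.48 ± 0.09, adjusted p = 9.6e-08). The immediate early gene EGR1 rose from 10.6 ± 0.264 to 40.8 ± 1.39 FPKM (1.85 ± 0.11, adjusted p = 5.4e-08). The complement gene C3 fell from 11.6 ± 0.2502 to 3.39 ± 0.144 FPKM (−1.52 ± 0.14, adjusted p = 9.5e-06). SOX10 (−0.07 ± 0.12, adjusted p = 0.825), MITF (0.05 ± 0.09, adjusted p = 0.832), SOX9 (0.12 ± 0.12, adjusted p = 0.680), DCT (−0.04 ± 0.09, adjusted p = 0.873) and BCL2L11 (−0.03 ± 0.12, adjusted p = 0.936) were not past the threshold.

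Of 25 genes of the unfolded protein and amino acid response 13 rose and 0 fell, and 16 and 0 adjusted over the list alone. The median was 0.41 and the list test gave adjusted p = 1.4e-14, and adjusted p = 0.00807 with an estimated correlation. HERPUD1 (1.56 ± 0.13, adjusted p = 1.8e-06), PDIA4 (1.11 ± 0.08, adjusted p = 2.3e-07) and ATF3 (1.06 ± 0.09, adjusted p = 6.1e-06) rose. GDF15 (1.47 ± 0.12, adjusted p = 2.2e-06) and SESN2 (0.55 ± 0.10, adjusted p = 0.00518), which are p53 targets as well as stress genes, were the 2 of 23 p53 targets that rose, and 0 fell. The median was 0.12 and the list test gave adjusted p = 0.00799, and adjusted p = 0.371 with an estimated correlation. Without overexpression library 3 the p53 list gave 0.0700 (range over the alternatives 0.00148 to 0.0700). Of 23 immediate early genes 6 rose and 1 fell, and 9 and 2 adjusted over the list alone. The median was 0.22 and the list test gave adjusted p = 0.00258, and adjusted p = 0.392 with an estimated correlation. Among them were EGR2 (0.67 ± 0.08, adjusted p = 0.000127) and NR4A3 (0.64 ± 0.12, adjusted p = 0.00445). MCF2L (1.55 ± 0.13, adjusted p = 3.5e-06), the sterol carrier STARD4 (0.84 ± 0.14, adjusted p = 0.00290), TNFAIP3 (0.69 ± 0.10, adjusted p = 0.000624), BHLHE40 (0.58 ± 0.10, adjusted p = 0.00399) and HIST1H4H (0.78 ± 0.11, adjusted p = 0.000424) rose.

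Of 19 BMP targets 4 rose and 0 fell, and 8 and 0 adjusted over the list alone. The median was 0.21 and the list test gave adjusted p = 0.000937, and adjusted p = 0.371 with an estimated correlation. The 4 were DLX2 (0.71 ± 0.09, adjusted p = 0.000181), ID1 (0.43 ± 0.11, adjusted p = 0.0376), ID2 (0.91 ± 0.21, adjusted p = 0.0230) and ID3 (0.53 ± 0.12, adjusted p = 0.0228). The count was 1 without empty vector library 1 or 3 or overexpression library 1 or 3, 2 without empty vector library 2 and 5 without overexpression library 2. ID1 gave 0.151, 0.111 and 0.104 without empty vector library 1, 2 or 3 and 0.105 without overexpression library 1 or 3 (range over the alternatives 0.0169 to 0.151). ID2 gave 0.108 and 0.111 without empty vector library 1 or 3 and 0.0959 and 0.0742 without overexpression library 1 or 3 (range 0.00726 to 0.111). ID3 gave 0.0787, 0.0927 and 0.0775 without empty vector library 1, 2 or 3 and 0.0871 and 0.0685 without overexpression library 1 or 3 (range 0.000193 to 0.139). SMAD6 (−0.12 ± 0.10, adjusted p = 0.605) and SMAD7 (0.35 ± 0.11, adjusted p = 0.112) were not past the threshold.

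Of 43 G2 and M phase genes 0 rose and 4 fell, and 0 and 14 adjusted over the list alone. The median was −0.25 and the list test gave adjusted p = 2.2e-12, and adjusted p = 0.388 with an estimated correlation. The 4 were UBE2C (−0.43 ± 0.10, adjusted p = 0.0192), ANLN (−0.47 ± 0.11, adjusted p = 0.0289), CENPA (−0.46 ± 0.12, adjusted p = 0.0408) and CDCA3 (−0.45 ± 0.12, adjusted p = 0.0440). The count was 0 without empty vector library 1, 2 or 3, 2 without overexpression library 1 and 1 without overexpression library 2. Of 33 extracellular matrix genes 0 rose and 7 fell, and 1 and 12 adjusted over the list alone. The median was −0.14 and the list test gave adjusted p = 9.1e-05, and adjusted p = 0.392 with an estimated correlation. COL5A1 (−0.50 ± 0.08, adjusted p = 0.00216) and COL6A2 (−0.63 ± 0.11, adjusted p = 0.00307) fell. The 7 became 2, 3 and 4 without empty vector library 1, 2 or 3 and 4 and 3 without overexpression library 1 or 2. Of 25 genes of the dedifferentiated melanoma state 1 rose and 5 fell, and 2 and 10 adjusted over the list alone. The median was −0.21 and the list test gave adjusted p = 0.000288, and adjusted p = 0.371 with an estimated correlation. NGFR (−0.97 ± 0.13, adjusted p = 0.000296), AXL (−0.50 ± 0.09, adjusted p = 0.00453) and CYR61 (−0.48 ± 0.09, adjusted p = 0.00663) fell, and the 5 were 3 without empty vector library 1, 2 or 3 or overexpression library 1. S1PR1 (−0.93 ± 0.10, adjusted p = 2.2e-05), the chemokine CCL2 (−0.90 ± 0.13, adjusted p = 0.000624), IGFBP2 (−0.89 ± 0.13, adjusted p = 0.000570), LOXL4 (−0.84 ± 0.10, adjusted p = 6.4e-05) and FST, an antagonist of the BMP family (−0.57 ± 0.10, adjusted p = 0.00249), fell too.

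The other 21 lists tested were not past the threshold with GDF6 overexpression, so 7 passed, and 11 did so without overexpression library 2. The 4 gained there were mitochondrially encoded genes, lower (adjusted p = 2.5e-05, against 0.119 with all libraries and a range of 2.5e-05 to 0.955 over the alternatives), S phase genes, lower (0.00230, against 0.0836, range 0.00230 to 0.366), bone and cartilage genes, higher (0.0342, against 0.0853, range 0.0342 to 0.345), and sterol synthesis genes, higher (0.0365, against 0.1002, range 0.0365 to 0.266). Cytosolic ribosomal proteins were lower without overexpression library 1 (0.0255) or 3 (0.00388), against 0.0905 (range 0.00388 to 0.9998). Glycolysis and hypoxia genes were lower without overexpression library 1 (0.0193) or 3 (0.0205), against 0.0836 (range 0.0193 to 0.704). Without a filter the S phase, glycolysis and mitochondrial lists passed too (0.0350, 0.0440 and 0.0470), and the S phase list also without empty vector library 1 (0.0168). Among the 21, median and mean or test differed in sign for TGF-beta targets, NF-kappaB genes and neuronal and glial genes. With GDF6 overexpression 297 genes were higher and 135 lower, and 21 and 1 of them by at least 2-fold. The 432 became 198, 237 and 211 without empty vector library 1, 2 or 3 and 263 without overexpression library 1. The share of higher genes among them was 68.8%, against 57.3% after quantile normalization and 49.3% after median-ratio scaling, and 26.6% of genes did not overlap, against 10% by chance.

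Genes that changed both in the libraries labelled GDF6 knockdown and with GDF6 overexpression numbered 346, and 173 of them changed in opposite directions, against 135 expected by chance, and 173 in the same direction, against 131 expected. Among the 346, 146 rose in both, 27 fell in both, 78 rose in the libraries labelled GDF6 knockdown and fell with overexpression, and 95 did the opposite. Fisher's exact test of direction, two-sided, gave p = 0.0146, and 0.0146 adjusted over 3 such tests, with an odds ratio of 0.533 for the same direction. EGR1, ID1, ID2, ID3 and DLX2 were among the 95, and HERPUD1, DDIT3, HSPA5 and GDF15 among the 146. The 173 in opposite directions became 70, 94 and 84 without empty vector library 1, 2 or 3 and 98 without overexpression library 1. Across genes the Pearson correlation of the 2 sets of fold changes was −0.01 and Spearman's −0.06. Genes that changed both with SMAD1 and with GDF6 overexpression numbered 220, and 170 changed in the same direction, against 48.5 expected (Fisher's exact test of direction, two-sided, p = 1.5e-17, and 2.3e-17 adjusted, odds ratio 14.6); 81, 98 and 89 did so without empty vector library 1, 2 or 3 and 103 without overexpression library 1. Both Fisher tests count genes as separate trials, though genes are not independent replicates. Their p-values therefore do not measure how well the directions would repeat in other cultures.

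Among the 181 genes with a change in all 3 comparisons, 53 were lower in the libraries labelled GDF6 knockdown, higher with SMAD1 and higher with GDF6 overexpression, and 54 had the opposite pattern. If the calls with overexpression, whose libraries the other 2 comparisons do not use, were independent of the others, 18.6 and 8.99 would be expected. Of the genes with the same 2 first changes, 8 and 27 went the other way with overexpression, against 8.46 and 19.8 expected. Genes changed with SMAD1 were more often changed with overexpression whatever the direction (odds ratio 3.63). The 53 became 26, 31 and 26 without empty vector library 1, 2 or 3 and 29 without overexpression library 1, and the 54 became 26, 35, 32 and 34. The 53 held ID1, ID2, ID3, DLX2, EGR1, TFAP2B, PTGS2 and SAMD11. The 54 held S1PR1, CCL2, IGFBP2, AXL, CYR61, FOSL1 and the caveolar gene CAV1. FOSL1 was at 45.1 ± 4.80, 173 ± 22.3 and 113 ± 3.79 FPKM in the EGFP knockdown libraries, those labelled GDF6 knockdown and those given SMAD1, and at 313 ± 15.2 and 233 ± 3.13 with the empty vector and GDF6 overexpression.

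The background of the knockdown groups was read by comparing the EGFP knockdown libraries with the empty vector libraries. IGFBP5, which binds insulin-like growth factors, was at 119 ± 17.0 against 0.279 ± 0.0289 FPKM (log2 fold change 6.54 ± 0.09, adjusted p = 3.4e-17). The hypoxia gene CA9 was at 119 ± 30.7 against 0.487 ± 0.156 FPKM (6.30 ± 0.19, adjusted p = 2.9e-13) and SPP1 at 87.6 ± 19.7 against 0.707 ± 0.196 (5.68 ± 0.14, adjusted p = 3.9e-14). IL24 (−3.93 ± 0.13, adjusted p = 1.1e-12), FOXC2 (−3.03 ± 0.10, adjusted p = 6.0e-13) and UBE2C, at 43.5 ± 4.99 against 355 ± 6.55 (−3.01 ± 0.10, adjusted p = 6.0e-13), fell. DCT rose (3.28 ± 0.09, adjusted p = 1.1e-13), as did MITF (0.58 ± 0.09, adjusted p = 2.0e-05). ID1 (−1.74 ± 0.11, adjusted p = 6.5e-10), SMAD6 (−2.20 ± 0.10, adjusted p = 3.2e-11), SMAD7 (−0.60 ± 0.11, adjusted p = 0.000177) and GDF6 (−0.78 ± 0.23, adjusted p = 0.00597) fell. ID2 (0.18 ± 0.21, adjusted p = 0.438), SOX10 (0.14 ± 0.12, adjusted p = 0.289) and SOX9 (0.28 ± 0.12, adjusted p = 0.0550) were not past the threshold. ID3 gave −0.03 ± 0.12, adjusted p = 0.834, and a log2 fold change of 0.31 with adjusted p = 0.0154 after quantile normalization (range over the alternatives 0.0154 to 0.930). SMAD1 gave −0.29 ± 0.09, adjusted p = 0.00953 (0.0503 without EGFP knockdown library 2, range 0.00102 to 0.121), and BCL2L11 0.38 ± 0.12, adjusted p = 0.0109 (0.0530 without EGFP knockdown library 3, range 0.00159 to 0.0719).

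Of 43 G2 and M phase genes 0 rose and 42 fell (adjusted p = 1.1e-11, and adjusted p = 0.227 with an estimated correlation), and of 41 S phase genes 0 rose and 37 fell (8.9e-10, and adjusted p = 0.227 with an estimated correlation). Of 41 cytosolic ribosomal proteins 0 rose and 38 fell (3.6e-05, and adjusted p = 0.679 with an estimated correlation). The ribosomal list gave 0.205 after quantile normalization (range over the alternatives 5.1e-07 to 0.205). Of 10 anti-apoptotic genes 1 rose and 8 fell (0.0172, and adjusted p = 0.227 with an estimated correlation), with 0.123 at a filter of 5 FPKM (range 0.00776 to 0.123). Of 33 extracellular matrix genes 29 rose and 1 fell, and 30 and 1 adjusted over the list alone (1.3e-10, and adjusted p = 0.131 with an estimated correlation). Of 14 histones 12 rose and 0 fell (1.5e-05, and adjusted p = 0.0554 with an estimated correlation). The other lists that rose, each with its 2 adjusted p-values in that order, were fibroblast markers with 12 and 1 (0.000173, and 0.0718), interferon-stimulated genes with 20 and 5 (0.000654, and 0.131), neuronal and glial genes with 10 and 3 (0.00497, and 0.136) and bone and cartilage genes with 6 and 2 (0.0379, and 0.227). The bone and cartilage list gave 0.266 after quantile normalization and 0.0804 after median-ratio scaling (range 0.0311 to 0.266).

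Medians and means or tests differed in sign for neural crest regulators, pro-apoptotic genes, Notch targets, p53 targets and glycolysis genes, which were not past the threshold. The immediate early list gave adjusted p = 0.115, and 0.0173 without a filter. Between these 2 groups 3719 genes were higher and 5121 lower, 1211 and 1414 of them by at least 2-fold. After quantile normalization 3923 were higher and 4706 lower, and after median-ratio scaling 4421 and 4269. The values did not overlap for 79.3% of genes, against 10% by chance. The median log2 fold change of all genes was −0.12, against 0.01 after median-ratio scaling and −0.07 after quantile normalization. The EGFP knockdown libraries differed from the empty vector libraries in 8840 genes and from the libraries labelled GDF6 knockdown in 7406.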

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

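The fit of the 9 knockdown libraries alone and the alternatives for genes changed in 3 comparisons were chosen after seeing the data; the other alternatives were planned. Counts of changed genes stayed within 1.5 times the reported ones under the other pseudocount, filters, scalings, variance prior and fits. With a change of at least 2-fold required as well, which can only remove genes, 1626 genes remained for the libraries labelled GDF6 knockdown, 369 for SMAD1 added, 1411 for SMAD1 against EGFP knockdown, 22 for GDF6 overexpression and 2625 for EGFP knockdown against the empty vector. With an estimated correlation the lists past the threshold numbered 0, 1, 0, 1 and 0 in the same order; the cause was not tested. Leaving out 1 library, which lowers the number of samples, gave 6860 to 7372, 2144 to 2821, 6789 to 7107, 198 to 431 and 8357 to 8586 changed genes in that order, and 6 to 10, 13 to 15, 11 to 11, 7 to 11 and 10 to 10 lists. It gave 1244 to 1529 changes in the libraries labelled GDF6 knockdown that reversed with SMAD1, 70 to 217 opposite changes between the GDF6 knockdown label and overexpression, and 81 to 187 same-direction changes between SMAD1 and overexpression. Of the genes changed in 3 comparisons it gave 26 to 65 for those lower in the libraries labelled GDF6 knockdown and higher in the others, and 26 to 68 for the opposite pattern. A block for the replicate number gave 7539, 2888, 7589, 417 and 8933 genes. Whether the numbers pair the samples was not settled. Correlations of residuals at the same number ran from −0.29 to 0.44, and not every library correlated best with its own number. Libraries numbered 1 did so, at 0.30 to 0.44, in every comparison except EGFP knockdown against the empty vector (−0.02). The 9 knockdown libraries alone gave 7316, 2659 and 7377 changed genes for the 3 comparisons they hold. Of 6099 alternative values for 420 named-gene results, 5809 kept their direction and side of the threshold, 252 were weaker, 37 stronger and 1 reversed; 50 of 328 called results lost the call at least once. The reversed one was ID3 in EGFP knockdown versus empty vector, with a log2 fold change of 0.31 after quantile normalization, where the reported one was −0.03 ± 0.12; the cause was not tested. Depth is unknown, so what depth limits was not tested.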

Other observations

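The tests of exchanged labels, carried-over fragments, scaling, fibroblasts, batch, pathway activity, SMAD1 signalling and secretory load, and the class II genes, were chosen after the results were seen. The genes of antigen presentation by MHC class II were read as a group without a list test. CD74, the chain that guides class II molecules, was at 1448 ± 169 FPKM with EGFP knockdown, 262 ± 58.9 in the libraries labelled GDF6 knockdown (log2 fold change −2.48 ± 0.17, adjusted p = 2.4e-09) and 669 ± 83.7 with SMAD1 (1.36 ± 0.17, adjusted p = 1.2e-05). HLA-DRA was at 81.7 ± 10.6, 14.03 ± 2.41 (−2.46 ± 0.13, adjusted p = 1.2e-10) and 38.4 ± 6.18 (1.39 ± 0.13, adjusted p = 5.2e-07). CIITA, the factor that switches these genes on, was at 14.3 ± 4.002, 2.74 ± 0.0356 (−2.005 ± 0.15, adjusted p = 7.3e-09) and 4.75 ± 0.787 FPKM (0.61 ± 0.15, adjusted p = 0.00627). Of 14 such genes, CIITA, CD74 and 12 HLA genes, 14 fell in the libraries labelled GDF6 knockdown, 13 rose with SMAD1, with HLA-DOA not past the threshold (0.10 ± 0.08, adjusted p = 0.389), and 14 were still lower than with EGFP knockdown. With GDF6 overexpression 0 of 14 passed. Between EGFP knockdown and empty vector libraries 3 rose, 4 fell and 7 were not past the threshold, with CIITA at −1.21 ± 0.15, adjusted p = 1.8e-06 and HLA-DRA at 0.34 ± 0.13, adjusted p = 0.0260. The HLA genes share sequence, so the value of any single one is uncertain.

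GDF6 was no lower in the libraries labelled GDF6 knockdown than with EGFP knockdown, although the ID genes were. An exchange of labels between these groups is argued against: the libraries given SMAD1 correlated better with those labelled GDF6 knockdown, by 0.0530 in the median, and their lowest pair, at 0.963, lay above their highest with EGFP knockdown, at 0.927. Fragments carried over from the overexpression libraries stay open: GDF6 varied more between empty vector libraries than 99.9% of genes of like level, but at percentiles of 22.4 and 34.7 in the EGFP knockdown libraries and those labelled GDF6 knockdown. A carry-over of 0.000242 of the overexpression level could give the whole GDF6 value of the EGFP knockdown libraries, and the lowest such ratio of another abundant gene, IL24, was 0.0408. The libraries given SMAD1 had a ratio of 1.2e-05, which an even carry-over into every library does not give. No biological explanation was tested.

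The EGFP knockdown libraries lay far from the empty vector libraries. The authors' scaling is argued against as the whole cause, since 8690 genes were changed after median-ratio scaling, 7988 of them with the same sign as before. Fibroblasts mixed into the culture are argued against as the source of the rises of PRRX1, by 74.1 FPKM, and S100A4, by 209 FPKM. There COL1A1, COL1A2 and COL3A1 reached at most 1.56 FPKM. A small admixture stays open, since 12 of 13 tested fibroblast markers were higher with EGFP knockdown and 1 lower. LUM, for example, had a mean of 9.54 against 1.11 FPKM, and DCN 5.59 against 0.408. A batch that separates the 9 knockdown libraries from the other 6 cannot be told apart from an effect of the knockdown constructs, because every library on that side carries a knockdown. Against the mean of the overexpression libraries, which did not make the calls, 70.0% of the 8840 changed genes lay on the same side in all 6 other knockdown libraries, as either would give.

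Genes of the unfolded protein and amino acid response were higher both in the libraries labelled GDF6 knockdown and with GDF6 overexpression. Each comparison has its own control. With EGFP knockdown 7 of the 25 list members were higher than with the empty vector and 14 lower, 9 of these by at least 2-fold. The median was −0.53 and the list test gave adjusted p = 0.377. A single library is argued against as the cause of the rise with overexpression, since at least 12 of the list rose whichever library was left out. Whether added SMAD1 takes back the rise was read in the libraries labelled GDF6 knockdown. There the 13 genes higher in both comparisons rose by log2 fold changes of at least 1.27. Adding SMAD1 took the median BMP target to 0.98 above EGFP knockdown, but changed these 13 by a median of 0.17, with a lowest of −0.46 for ATF3. All 13 stayed higher than with EGFP knockdown, so added SMAD1 did not undo the rise. This cannot decide on loss of SMAD1 signalling as its cause, because the BMP targets went past the control level. Whether such a gain raises the same genes is not known. Other activity of the GDF6 pathway on these genes stays open. The 13 had the same sign in both comparisons and 0 had opposite signs, but this restates the pattern, and GDF6 was not lower in the libraries labelled GDF6 knockdown. For the rise with overexpression SMAD1 signalling also stays open, since SMAD1 was added only where these genes were already high. A load of protein made for secretion stays open, since GDF6 ranked 6 by FPKM in the overexpression libraries but no library overexpresses another secreted protein.

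Other splits of the 6 libraries of each comparison were counted. With 10 splits the share of splits that reach the real count cannot be under 0.1, so they decide nothing. The real split gave 7406, 2799, 7456, 432 and 8840 genes, 1 of 10 splits reached that count, and the highest count of any other split was 0 in each comparison.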
